A study of Rattus norvegicus with 9 samples.

How the data were processed

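Small RNA was sequenced from the serum of male Wistar rats in 9 libraries, 3 from each of 3 groups. Per the labels' protocols, RNA was isolated with a miRNeasy serum kit and libraries were made with the QIAseq miRNA kit. The series text gives single-end Illumina reads of 50 bases. The values deposited by the authors are whole-number read counts per mature miRNA, for 567 miRNAs in each library. A matrix of the whole series was deposited as well, and 0 of its values differed from those of the single libraries. The genome build was mRatBN7.2, per the submitters' processing notes. The aligner, the counting tool, the miRNA annotation and any read filter are not given in the sources used here. The kit adds molecular identifiers, but no source says whether they were used to collapse duplicate reads. PCR reads without molecular identifiers are not independent molecules, so intervals and floors given here cover counting error only.

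Groups and replicate numbers were taken from the sample titles. The treatment label and the treatment protocol are worded alike for all 9 samples, controls included, and what the control animals received is not stated. The series text assigns animals to groups at random, and the titles name separate samples. Within each group, pairs of libraries had a chi-square per degree of freedom of at least 31.2, the lowest being LPD 1 and LPD 2. Where reads are not independent molecules, as in LPD, this does not show that the libraries came from different animals. The p-values measure the spread between these samples, and in the fits all 3 groups share 1 estimate of it. Pairs of LPD libraries correlated in log2 CPM by 0.719 to 0.769, against 0.880 to 0.981 in Control and 0.952 to 0.974 in EPD. The shared estimate may therefore understate the spread within LPD. No label gives a sequencing date or batch.

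miRNAs were kept with edgeR's filterByExpr by group (at least 10 counts, at least 15 in total), which left 294. Library sizes were scaled by TMM, and the CPM values printed here, counts scaled to a common library size, were computed from the deposited counts with those factors. The 3 groups were fitted together with edgeR's robust quasi-likelihood model, without covariates. Each pair of groups and the 3 groups together were tested, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Standard errors (SE) of log2 fold changes came from the same fit, and means carry the SD over n = 3 libraries. Depth, detection, the share of the 10 most abundant miRNAs and a haemolysis index (a measure of red cell lysis) were compared by exact two-sided permutation tests, 12 in all. The index is the log2 ratio of miR-451-5p to miR-23a-3p with a prior of 0.5 counts. With 3 libraries against 3, such a test cannot give a p under 0.1. Shares of counts in single libraries carry Wilson intervals at 95%.

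For a miRNA with no count in any library of a group, the fitted fold is not printed. The exception is miR-9a-5p with LPD 3 left out, where the fitted value is given as an alternative and not as a measured fold. A count of 0 allows up to 3 counts per library, which stands for 1.73 to 3.83 CPM in the Control and EPD libraries and for 9.94 to 19.8 CPM in the LPD libraries. There 3 counts are less than 1 estimated molecule, and 3 molecules stand for 244 to 662 CPM, so no bound on a fold is printed for miRNAs absent from LPD.

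The miRNAs named in the text follow a fixed rule. Among miRNAs past the threshold, with a group mean of at least 50 CPM and no overlap between the groups, the 10 largest changes in each direction were taken. Where fewer than 5 qualified, the 5 smallest p in each direction were added. A panel of 16 miRNAs was always included, and up to 4 called members of a list served as its examples. A miRNA chosen after its values were seen is described as such. Names were matched after removing the species prefix, and an entry without an arm matched a listed name once. Arms or copies with equal counts cannot be told apart, and 6 miRNAs with at least 50 counts had the same 9 counts as another. None of these 6 is named. Members of 1 seed family, such as let-7, differ by few bases, so reads may have been split between them in a way the sources do not describe.

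The 15 miRNA lists covered erythrocytes, platelets and megakaryocytes, leukocytes, liver, muscle, brain, the Dlk1-Dio3 cluster, earlier Parkinson literature, inflammation, hypoxia with p53 and mitochondrial stress, the let-7 family, the miR-17 family clusters, epithelium, pancreas, and vessel wall with fibroblasts. They were written from general knowledge and overlap. Of the tested members, 10 of 16 in the erythrocyte list, 3 of 12 in the liver list, 17 of 22 in the Parkinson list, 11 of 18 in the vessel wall list, 7 of 18 in the epithelium list and 0 of 9 in the let-7 list stand in another list. Each list with at least 3 tested members was tested against the other miRNAs with camera at its preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. fry asks whether the members of a list moved, on balance, one way, without comparing them with other miRNAs.

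The number of different molecules behind each library was estimated from how many miRNAs had no count in it, given the mean profile of the other Control and EPD libraries. Counts per molecule are the total divided by that estimate. Dividing each library's counts by its counts per molecule and rounding gave 1 of the alternatives.

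Alternatives were other scalings (DESeq2's size factors, library totals, TMM without the erythrocyte list), other filters, DESeq2's Wald test, limma-voom, a fit of only the groups compared, the replicate number as a block, the haemolysis index as a covariate and leaving out each library in turn. The correlation of changes in EPD and LPD was set beside 100 simulations of unchanged groups against the same controls. Neighbouring miRNA genes were grouped with a RefSeq gene table of assembly GRCr8, used only for names and neighbours, and 269 of the 294 miRNAs matched a single gene there. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

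The fit was tested on simulated counts with 200 changed miRNAs. Of changed miRNAs that were tested in EPD against Control, 15% were called at a 2-fold, 40.9% at a 4-fold and 78.6% at an 8-fold change, with 4 false calls among 193 unchanged. In LPD against Control these were 9.30%, 28.6% and 51.4%, with 2 false calls among 202. In LPD against EPD they were 11.4%, 26.3% and 67.6%, with 1 among 194. The simulated counts had the LPD totals but no molecules read many times, so these rates may not hold for the real LPD libraries. A simulated library of 8000 molecules was estimated at 7665. It was drawn from the mean profile that the estimate assumes, so it does not test that assumption.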

Results

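Serum miRNAs were compared in rats given rotenone, an inhibitor of mitochondrial complex I, as a model of Parkinson's disease. There were 3 groups of 3 libraries. Animals of the early group (EPD) received rotenone at 2 mg per kg per day for 10 days, those of the late group (LPD) for more than 40 days, and the rest were controls (Control). The LPD libraries held 215841 ± 86358.7 counts (mean ± SD, n = 3), against 1272927 ± 233040 in Control and 1469349 ± 290112 in EPD. Of 567 miRNAs, 161 ± 18.7 had at least 10 counts in LPD, against 305 ± 33.6 in Control and 302 ± 9.50 in EPD. Control and EPD libraries were also thinned at random to the LPD totals. At those of LPD 2 and LPD 3 they kept 173 to 212 and 151 to 182 miRNAs at 10 counts, against 144 and 158. At the total of LPD 1 all kept more than its 181 (up to 236). Reads in LPD may repeat the same molecules, so this does not show how much of the drop went with the lower totals. Every LPD library lay below every other library in both measures, which gives exact permutation p = 0.1, the smallest p that 3 against 3 libraries can reach (adjusted over 12 tests, 0.24). EPD and Control were not told apart by totals (exact p = 0.3) or by detected miRNAs (exact p = 0.9).

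**Figure D1:**
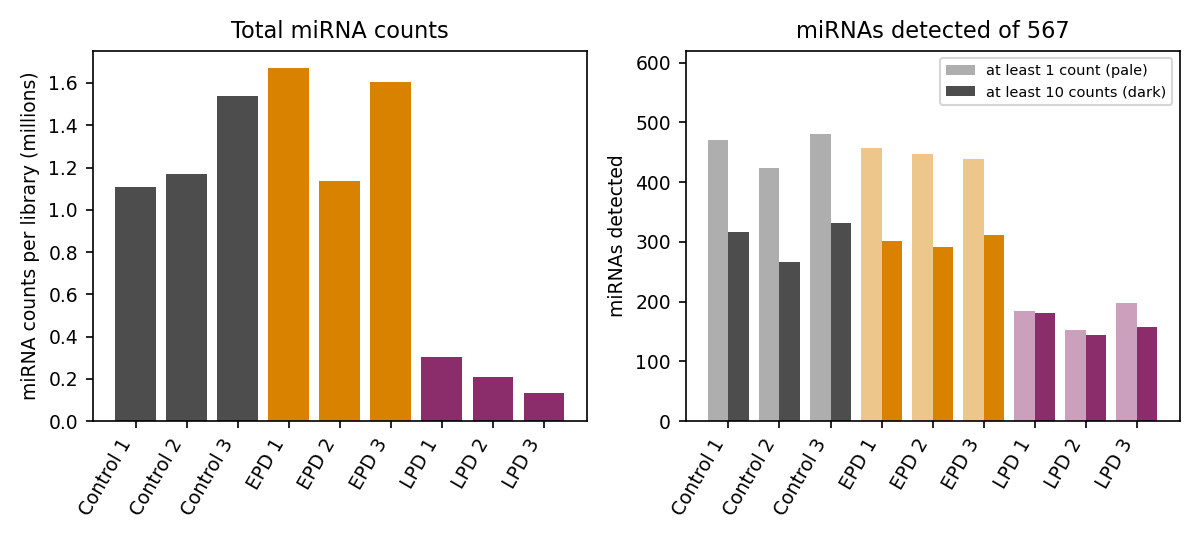
Bars show the total miRNA counts of each library and the number of miRNAs detected with at least 1 count (pale) or at least 10 counts (dark) out of 567, for Control, EPD and LPD. LPD libraries held 305019, 209895 and 132609 counts.

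The LPD libraries also lacked miRNAs with few counts. miRNAs with 1 to 9 counts numbered 3, 9 and 39 in the LPD libraries, against 153, 157 and 150 in Control and 155, 155 and 127 in EPD. The counts per estimated molecule were 36.7, 49.1 and 12.3 in LPD and between 1.07 and 3.09 in the other libraries. If serum of the LPD group had the mean profile of Control and EPD, an estimated 8315, 4279 and 10755 molecules stood behind the 3 LPD libraries. Of the 294 miRNAs that could be tested, 124 had counts in all 9 libraries.

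**Figure D2:**
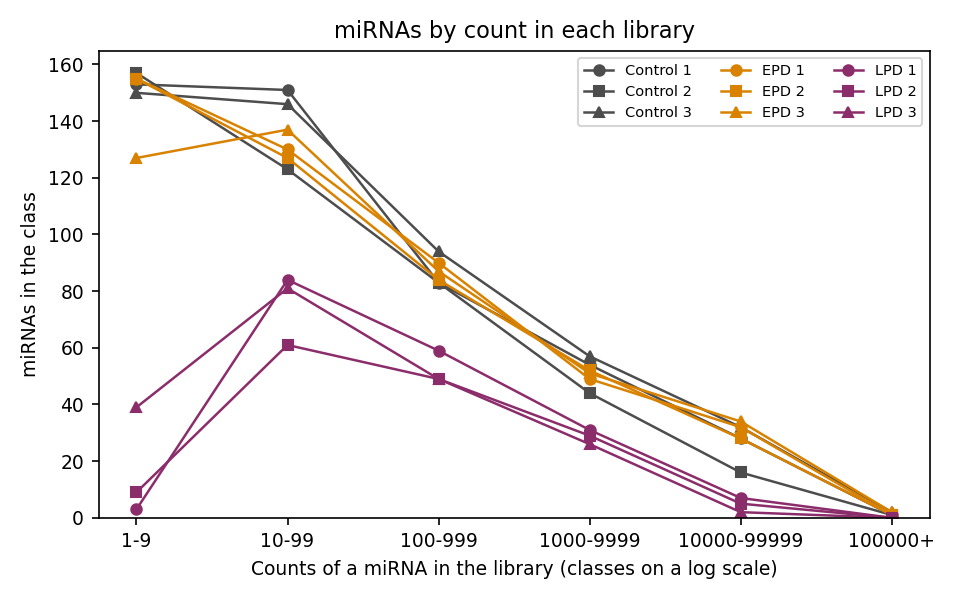
Lines show how many miRNAs of each library fall in each class of counts, from 1 to 9 counts upward on a log scale, in the Control, EPD and LPD groups. In the lowest class LPD libraries have 3, 9 and 39 miRNAs.

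miR-16-5p, abundant in red cells, took 13.1 ± 6.97% of the counts in Control, 20.9 ± 8.75% in EPD and 29.8 ± 4.55% in LPD. Its share was 16.5, 5.14 and 17.8% in the Control libraries and 30.8, 17.5 and 14.4% in the EPD libraries. The step from Control to EPD thus rested on Control 2 and EPD 1. The 10 most abundant miRNAs of a library together took 61.5 ± 10.7%, 58.7 ± 2.41% and 67.3 ± 3.12% (exact p = 1 for EPD against Control, 0.4 for LPD against Control and 0.1 for LPD against EPD). The haemolysis index, the log2 ratio of the red cell miRNA miR-451-5p to miR-23a-3p, was -3.71 ± 0.89 in Control and stood 0.71 higher in EPD and 0.71 higher in LPD, with SDs of 1.44 and 0.40 (exact p = 0.6 for EPD against Control, 0.3 for LPD against Control and 1 for LPD against EPD). Single libraries moved the haemolysis index, EPD against Control, to -0.11 without EPD 1, 0.28 without Control 2, 1.17 without Control 3 and 1.22 without EPD 3, and the haemolysis index, LPD against Control, to 0.27 without Control 2 and 1.16 without Control 3. With miR-191a-5p in place of miR-23a-3p the index was higher in LPD by 3.19 than in Control and by 3.13 than in EPD (exact p = 0.1 each). miR-191a-5p itself fell in LPD, as described below.

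Control 2 stood apart by miRNAs of the liver. The hepatocyte miRNA miR-122-5p made up 44.3% of its counts (Wilson interval 44.2 to 44.4%), against 2.47% (2.44 to 2.50%) and 5.14% (5.11 to 5.18%) in the other controls. In EPD it made up 1.07, 1.35 and 4.43% and in LPD 1.44, 1.73 and 4.23%. Other liver miRNAs were raised in the same library: miR-192-5p with 30540 CPM against 6137 and 9511, miR-194-5p with 3743 against 1058 and 1091, miR-802-5p with 525 against 42.3 and 98.7. The 11 tested liver miRNAs other than miR-122-5p were higher in Control 2 by a median of 1.92 log2, and 9 of them lay above both other controls. This library therefore weighs on comparisons of these miRNAs with Control.

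**Figure D3:**
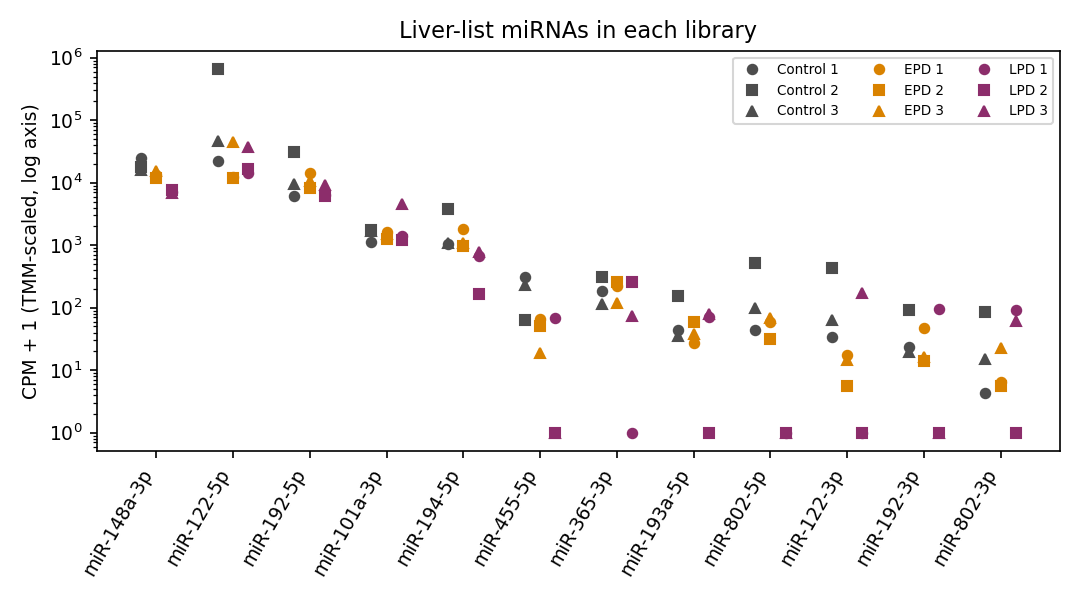
Points show the 12 tested miRNAs of the liver list in each library, as TMM-scaled CPM plus 1 on a log axis, with no counts drawn at 1. Control 2 has 30540 CPM of miR-192-5p, against 6137 and 9511 in the other controls.

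After 10 days of rotenone no miRNA passed the test. The smallest adjusted p was that of miR-199a-3p, found in platelets and fibroblasts. It had 11949 ± 1404 CPM in EPD against 39038 ± 15664 in Control (log2 fold change -1.71, SE 0.33, adjusted p = 0.179, n = 3 each), and was lower in all 3 EPD libraries than in any control. It passed with DESeq2 (-1.75, adjusted p = 1.3e-04), when only miRNAs with counts in all 9 libraries were kept (-1.78, adjusted p = 0.0268) and without Control 2 (-1.80, adjusted p = 0.0483). These were 3 of the 15 alternatives run for single miRNAs, and in the others it did not pass. The smallest adjusted p of any miRNA was 0.995 with library totals, 0.994 without EPD 2 and 0.851 without EPD 1. Higher values in EPD with the smallest p were those of miR-93-5p (log2 fold change 0.81, SE 0.32), the lymphocyte miRNA miR-150-5p (0.76, SE 0.31), the myeloid and platelet miRNA miR-223-3p (0.84, SE 0.39), miR-25-3p (0.74, SE 0.37) and the red cell miRNA miR-486 (1.13, SE 0.63). Lower values were those of miR-152-3p (-0.93, SE 0.32), miR-122-5p (-3.41, SE 1.23), the smooth muscle miRNA miR-143-3p (-0.82, SE 0.31) and miR-351-5p (-1.53, SE 0.62). The adjusted p of each of these 9 was 0.995. Some rested on 1 library: miR-122-5p stood at -0.50 without Control 2, at -4.32 without EPD 3 and at -2.62 with the replicate number as a block, miR-486 at 0.08 without EPD 1, and miR-223-3p at 1.45 without Control 2. The test was edgeR's quasi-likelihood F-test over 294 miRNAs, of which 0 were called and 11 had an unadjusted p under 0.05. DESeq2 called 1 and limma-voom 0. Fitting only the 2 groups gave 0 calls, but 35 of 301 miRNAs then had an unadjusted p under 0.05. On counts per molecule 0 were called, with 35 of 261 at such a p. Of the 294 miRNAs 38 (12.9%) did not overlap between EPD and Control, beside 10% by chance.

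Other miRNAs chosen in advance gave these values in EPD against Control. For red cells, miR-451-5p had a log2 fold change of 1.13 (SE 0.67) and miR-16-5p of 0.76 (SE 0.43), and the reference miR-23a-3p of -0.07 (SE 0.29). Without EPD 1 miR-451-5p stood at 0.02. The muscle miRNAs miR-1-3p and miR-133a-3p had -2.01 (SE 1.28) and -2.46 (SE 1.43), with -1.33 and -1.67 without Control 1 and -3.87 and -3.81 without EPD 3, and miR-1-3p -2.85 with the replicate block. The neuronal miR-9a-5p had -0.70 (SE 1.44, without EPD 1 -1.43) and miR-7a-5p, which represses alpha-synuclein, 0.11 (SE 0.40). miR-124-3p, a neuronal miRNA, had 2 counts in EPD 2 and none elsewhere, and was not tested. miR-155-5p, induced by inflammation, had 0.03 (SE 0.40), the endothelial miR-126a-3p 0.09 (SE 0.32), miR-21-5p -0.26 (SE 0.39), the hypoxia-induced miR-210-3p 0.26 (SE 1.16) and the p53-induced miR-34a-5p 0.41 (SE 1.14). All had adjusted p of 0.995. Changes near 0 turned in some alternatives: miR-23a-3p without Control 2 (0.33), EPD 1, EPD 3 or any LPD library and with library totals, miR-155-5p without Control 2 (-0.08) or EPD 2 and over miRNAs with counts in all 9 libraries, and miR-126a-3p without EPD 2 (-0.16).

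Of 15 lists, 6 passed the camera test with the preset correlation in EPD against Control. Erythrocyte miRNAs stood higher than the others (11 of 16 positive, median log2 fold change 0.41, adjusted p = 0.0126), as did those of epithelium (14 of 18, 0.27, adjusted p = 0.0209). Lower were the miRNAs of the imprinted Dlk1-Dio3 cluster (12 of 12 negative, median -1.24, adjusted p = 0.0126), of liver (12 of 12, -0.86, adjusted p = 0.0209), of muscle (4 of 5, -1.84, adjusted p = 0.0209) and of vessel wall and fibroblasts (15 of 18, -0.65, adjusted p = 0.0327). With an estimated correlation none of the 6 passed (adjusted p = 0.578 each), and fry called 0 of 15. No member of any list passed over all tested miRNAs. Adjusted over the list alone, miR-199a-3p was lower in the platelet list and in the vessel wall list. The remaining lists had adjusted p of 0.116 (leukocyte), 0.237 (miR-17 clusters), 0.317 (inflammation and let-7) and 0.975 (platelet, brain, Parkinson literature, hypoxia with p53 and mitochondrial stress, and pancreas). For the miR-17 clusters the median was -0.06 although the test pointed up, and for platelet and pancreas the medians were 0.04 and 0.09 although the test pointed down.

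These list results rested on single libraries. Without Control 2 the calls for erythrocyte (adjusted p = 0.353), liver (0.927), epithelium (0.667) and vessel wall (0.813) were lost, while Dlk1-Dio3 (1.45e-11) and muscle (0.00541) stayed. Without Control 1 Dlk1-Dio3 (0.278) and muscle (0.0841) were lost. Without EPD 1 only Dlk1-Dio3 was called (0.00260), and erythrocyte (0.568), liver (0.0768), muscle (0.0944), epithelium (0.0507) and vessel wall (0.568) were lost. Without EPD 2 liver was lost (0.0883), and without EPD 3 liver (0.0693) and vessel wall (0.0782). The vessel wall call was also lost without LPD 1 (0.0668), LPD 2 (0.0775) or LPD 3 (0.0850) and with the replicate number as a block (0.0690). Liver (0.178), epithelium (0.178) and vessel wall (0.164) were lost when only miRNAs with counts in all 9 libraries were kept, and muscle (0.0545) on counts per molecule.

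In the LPD libraries, after more than 40 days of rotenone, a group of abundant miRNAs had lower scaled counts than in Control. miR-125b-5p, an inflammation and vessel wall miRNA, fell from 13621 ± 1704 CPM in Control to 2179 ± 398 in LPD (log2 fold change -2.64, SE 0.25, adjusted p = 5.72e-04). miR-191a-5p fell from 49934 ± 14370 to 9896 ± 3164 (-2.33, SE 0.45, adjusted p = 0.00522) and miR-199a-3p from 39038 ± 15664 to 11214 ± 2712 (-1.80, SE 0.33, adjusted p = 0.00522), both from the platelet list. miR-29a-3p, which represses collagens, fell from 39184 ± 20227 to 11006 ± 3577 (-1.83, SE 0.41, adjusted p = 0.00828, without Control 2 -1.24). miR-148a-3p, from the liver and pancreas lists, fell from 19618 ± 4647 to 7237 ± 530 (-1.44, SE 0.25, adjusted p = 0.00522). The cartilage miRNA miR-140-3p fell 15.5-fold, from 37179 ± 18944 to 2403 ± 1178 (-3.95, SE 0.54, adjusted p = 0.00522), and was chosen after its values were seen. Of the epithelium list, which did not pass as a whole (adjusted p = 0.422), miR-205 (-2.05, SE 0.48, adjusted p = 0.0102), miR-182 (-2.19, SE 0.55, adjusted p = 0.0126) and miR-183-5p (-3.14, SE 0.76, adjusted p = 0.0104, without Control 1 -2.41) fell as well. The last 2 also stand in the erythrocyte list. miR-19b-3p of the miR-17 clusters fell from 1800 ± 264 to 608 ± 66.4 (-1.57, SE 0.31, adjusted p = 0.00550). Each of these 10 passed in all 15 alternatives run for single miRNAs. Other lower miRNAs passed in fewer of the 15, such as miR-203a-3p in 12, miR-29b-3p in 11, miR-146a-5p and miR-200a-3p in 9, miR-27b-3p in 8 and miR-342-3p in 4.

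Fewer miRNAs rose in LPD over Control. miR-6216 rose from 14.7 ± 3.88 to 364 ± 303 CPM (log2 fold change 4.62, SE 0.92, adjusted p = 0.00531, without LPD 1 5.29, without LPD 2 3.71). In the LPD libraries 3 estimated molecules stood for 365, 662 and 244 CPM, so its LPD mean rested on few molecules. A single molecule there would already have stood above its Control mean, so the size of this rise is not well determined. miR-10b-5p, encoded in a Hox cluster, rose from 970 ± 25.0 to 3030 ± 1074 (1.64, SE 0.34, adjusted p = 0.00610), and miR-126a-5p of endothelium and platelets from 3799 ± 1285 to 10889 ± 2447 (1.52, SE 0.32, adjusted p = 0.00658). miR-92a-3p of the miR-17 clusters rose from 2138 ± 230 to 6029 ± 2359 (1.50, SE 0.36, adjusted p = 0.0102). let-7a-5p rose from 8305 ± 1689 to 19579 ± 6119 (1.24, SE 0.31, adjusted p = 0.0126). These 5 also passed in all 15 alternatives. Others rested on single libraries. let-7e-5p rose by 1.81 (adjusted p = 0.0155, without Control 3 0.0564) and let-7d-5p by 1.23 (adjusted p = 0.0149), which was lost without Control 3 (0.0536) or LPD 2 (0.0510) and on counts per molecule (0.0698). miR-486 rose by 2.18 (adjusted p = 0.0264), which was lost without Control 1 (0.0664), Control 2 (0.0796), Control 3 (0.0655) or LPD 2 (0.0776). miR-223-3p rose by 1.17 (adjusted p = 0.0418), which was lost without Control 1, Control 3, EPD 2, EPD 3, LPD 1 or LPD 2 (0.0515 to 0.138), with the replicate block (0.0517) and on counts per molecule (0.0877), and which stood at 1.86 without Control 2. miR-1306-5p (2.06, adjusted p = 0.0385), miR-151-3p (1.39, adjusted p = 0.0392) and miR-423-5p (1.31, adjusted p = 0.0178) rose too. Their highest adjusted p when a library was left out were 0.129 (lost without any control, EPD 2 or EPD 3), 0.146 (Control 1, Control 3, EPD 2, EPD 3 or LPD 2) and 0.0644 (Control 1, Control 3 or LPD 2), and all 3 were lost on counts per molecule. With the replicate block miR-1306-5p (0.126) and miR-151-3p (0.113) were lost as well. The opposite arms miR-10b-3p, miR-151-5p and miR-92a-1-5p had 40.5, 44.7 and 5.87 CPM in Control and no count in LPD. They were called lower, but these means lay below the level of 3 estimated molecules in LPD, so their absence stays open.

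**Figure D4:**
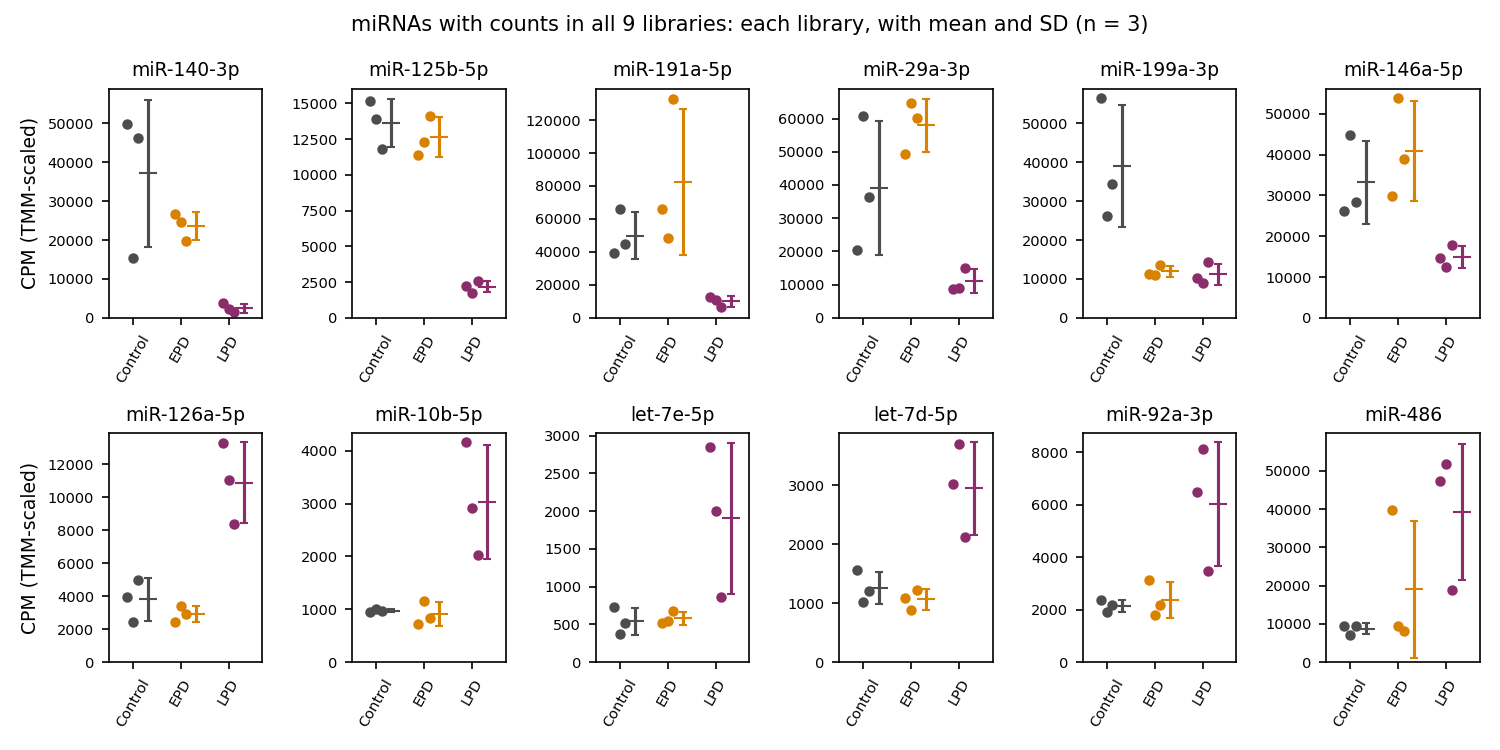
Points show 12 miRNAs in each library of Control, EPD and LPD as TMM-scaled CPM, with the mean and SD of 3 libraries. miR-125b-5p has 13621 CPM in Control and 2179 in LPD.

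In LPD against Control edgeR called 109 of 294 miRNAs, 13 higher and 96 lower (127 at an unadjusted p under 0.05). DESeq2 called 120 (26 higher, 94 lower) and limma-voom 96 (10 and 86). Of the 96 lower miRNAs, 64 had no count in any LPD library, 5 had none in 1 or 2 of them, and 27 had counts in all 9 libraries, as had 12 of the 13 higher ones. Fitting only the 2 groups gave 52 calls (8 higher, 44 lower), keeping only miRNAs with counts in all 9 libraries gave 38 (16 and 22), and counts per molecule gave 35 (8 and 27). In all, 142 miRNAs (48.3%) did not overlap between the groups, beside 10% by chance.

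Among the called miRNAs with no count in LPD, those with the highest means in Control were the hepatocyte miRNA miR-802-5p (222 ± 264 CPM, but 70.5 without Control 2), miR-322-3p (201 ± 126) and miR-324-5p (176 ± 51.4). Next came miR-127-3p (123 ± 85.1 CPM, without Control 1 80.9), miR-379-5p (90.1 ± 77.9, without Control 1 46.8) and miR-134-5p (79.5 ± 37.4), all of the Dlk1-Dio3 cluster. miR-324-3p had 69.4 ± 3.84 CPM in Control, miR-22-5p 58.8 ± 21.9, miR-672-5p 54.4 ± 29.1 and miR-99b-3p 52.6 ± 12.2. The called brain miRNAs with no count in LPD were low in Control as well, such as miR-219a-5p with 29.0 ± 21.4 CPM (17.0 without Control 3), miR-138-5p with 19.2 ± 2.50 and miR-132-3p with 10.3 ± 3.46. The call of miR-132-3p was lost with DESeq2 (0.0681) and without LPD 1, LPD 2 or LPD 3 (up to 0.105). In the LPD libraries 3 estimated molecules stood for 365, 662 and 244 CPM, and 0 of the 64 had a mean in Control above any of these, so no fold is given for them. On counts per molecule 43 of these 64 could be tested and 0 were called, whereas 23 of the 27 lower miRNAs with counts in all 9 libraries stayed. The molecules were estimated from the number of miRNAs without counts, so these losses do not test the absence of the 64, which stays open.

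Of the miRNAs chosen in advance, miR-223-3p and miR-34a-5p were called in LPD against Control. The p53-induced miR-34a-5p fell from 469 ± 197 to 26.4 ± 45.7 CPM (log2 fold change -4.31, SE 1.39, adjusted p = 0.0365), which was lost without Control 1 (0.0609), Control 2 (0.0796), Control 3 (0.0691), EPD 1 (0.0526), EPD 2 (0.0640), EPD 3 (0.0604) or LPD 2 (0.0644). LPD 3, with 12 counts, was the only LPD library in which it was found. At 12.3 counts per estimated molecule in LPD 3, this is about a single molecule, so the size of the fall is not well determined. The log2 fold change of miR-34a-5p stood at -3.61 without LPD 1, at -3.73 without LPD 2, at -3.63 on counts per molecule and at -5.05 with the replicate block. miR-451-5p had a log2 fold change of 0.86 (adjusted p = 0.357), miR-23a-3p of 0.07 (0.851, without Control 3 -0.18), miR-7a-5p of -0.68 (0.229), miR-155-5p of 0.40 (0.485) and miR-21-5p of 0.67 (0.226). The muscle miRNAs had 0.14 (miR-1-3p, adjusted p = 0.930; 0.77 without Control 1, -0.24 without Control 2, -1.68 without LPD 3, -0.75 with the replicate block) and -2.05 (miR-133a-3p, adjusted p = 0.308; -1.32 without Control 1, -1.44 without LPD 2, -3.88 without LPD 3, -3.14 with the block). miR-16-5p had 1.14 (adjusted p = 0.0660) and passed with DESeq2 size factors (0.0301), with DESeq2 (0.0111), without EPD 1 (0.0258) and without LPD 3 (0.0344). miR-122-5p had -3.43 (adjusted p = 0.0568) and passed with DESeq2 (0.0134), without Control 1 (0.0255) and without Control 3 (0.0404), but stood at -0.47 without Control 2, at -2.58 with the block and at -2.81 with library totals. miR-210-3p had -3.14 (adjusted p = 0.0933; -2.50 without LPD 2, -2.52 without LPD 3, -4.15 with the block) and passed without LPD 1 (0.00499), the only LPD library with counts of it, with DESeq2 (0.0400) and on counts per molecule (0.0354). miR-126a-3p had 0.50 (adjusted p = 0.278, without LPD 3 0.0361) and miR-150-5p 0.39 (adjusted p = 0.365, without LPD 3 0.0411). miR-9a-5p had 0.30 (adjusted p = 0.885; 0.95 without LPD 1, 0.89 without LPD 2, -0.69 with the block) and was called lower without LPD 3 (adjusted p = 0.0233), the only LPD library with counts of it.

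Of the lists, only let-7 passed in LPD against Control (higher, 7 of 9 positive, median log2 fold change 0.51, adjusted p = 0.00118), with let-7a-5p, let-7d-5p and let-7e-5p as its 3 called members. The call was lost with an estimated correlation (adjusted p = 0.906), and when only miRNAs with counts in all 9 libraries were kept (adjusted p = 0.142). Epithelium had 10 of 18 members lower and none higher (adjusted p = 0.422), Parkinson literature 8 of 22 lower (0.806), Dlk1-Dio3 6 of 12 lower (0.419), brain 4 of 8 lower (0.686), hypoxia with p53 3 of 14 lower (0.686), liver 2 of 12 lower (0.806), muscle 1 of 5 lower (0.806) and pancreas 1 of 3 lower (0.806). Members went both ways in the erythrocyte list (2 higher and 5 lower of 16, adjusted p = 0.161), platelet (3 and 3 of 14, 0.251), leukocyte (1 and 4 of 12, 0.419), inflammation (1 and 5 of 16, 0.806), miR-17 clusters (1 and 6 of 18, 0.806) and vessel wall (2 and 4 of 18, 0.686). Over all tested miRNAs, 96 of 294 were called lower and 13 higher. All called members of the Dlk1-Dio3 and brain lists had no count in any LPD library, an absence that stays open. Adjusted over the list alone, 4 erythrocyte members were higher and 5 lower, 2 members of the hypoxia list were lower, and the counts of the other lists stayed. The test pointed up although the median was negative for leukocyte, inflammation, miR-17 clusters, pancreas and vessel wall. Without Control 2 platelet (higher, 0.0477), Dlk1-Dio3 (lower, 0.0477) and epithelium (lower, 0.0306) passed too, and without LPD 1 platelet (higher, 0.0279). fry called 11 lists, all lower.

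Between the stages, LPD against EPD gave much the same miRNAs. miR-125b-5p fell from 12622 ± 1392 CPM in EPD to 2179 ± 398 (log2 fold change -2.53, SE 0.25, adjusted p = 7.91e-04) and miR-191a-5p from 82382 ± 44332 to 9896 ± 3164 (-3.06, SE 0.46, adjusted p = 0.00576). miR-29a-3p fell from 58032 ± 7950 to 11006 ± 3577 (-2.40, SE 0.42, adjusted p = 0.00576) and its relative miR-29b-3p from 6257 ± 621 to 1061 ± 845 (-2.56, SE 0.55, adjusted p = 0.00791, without LPD 3 -3.25). miR-146a-5p, induced by NF-kB, fell from 40925 ± 12217 to 14994 ± 2721 (-1.45, SE 0.32, adjusted p = 0.00842). Of the epithelium list, which did not pass as a whole (adjusted p = 0.147), miR-203a-3p (-2.27, SE 0.56, adjusted p = 0.0126), miR-205 (-2.35, SE 0.49, adjusted p = 0.00699), miR-182 (-2.73, SE 0.56, adjusted p = 0.00660) and miR-183-5p (-3.28, SE 0.76, adjusted p = 0.00992) fell. Chosen after their values were seen, miR-140-3p fell 9.85-fold (-3.30, SE 0.53, adjusted p = 0.00576) and miR-30d-5p 2.61-fold (-1.38, SE 0.27, adjusted p = 0.00591). miR-126a-5p rose from 2921 ± 473 to 10889 ± 2447 (1.90, SE 0.33, adjusted p = 0.00576), miR-10b-5p from 908 ± 221 to 3030 ± 1074 (1.74, SE 0.35, adjusted p = 0.00591), let-7d-5p from 1064 ± 175 to 2951 ± 793 (1.47, SE 0.32, adjusted p = 0.00807) and miR-6216 from 22.8 ± 9.04 to 364 ± 303 (3.99, SE 0.89, adjusted p = 0.00829, without LPD 2 2.99). All of these passed in all 15 alternatives. For miR-6216 the LPD mean again rested on few estimated molecules, so the size of its rise is not well determined. Other lower miRNAs passed in fewer of the 15, such as miR-29c-3p in 11, miR-148a-3p in 7, miR-128-3p and miR-200a-3p in 5 and miR-146b-5p in 4.

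Other miRNAs that rose from EPD to LPD rested on single libraries. miR-151-3p (log2 fold change 1.98, adjusted p = 0.0102) was lost without EPD 2 (0.0518). let-7e-5p (1.72, adjusted p = 0.0198) was lost without any EPD library, LPD 1 or LPD 2 (up to 0.0750), let-7a-5p (1.19, adjusted p = 0.0165) without EPD 1, EPD 2, LPD 1 or LPD 2 (up to 0.0715) and miR-92a-3p (1.35, adjusted p = 0.0171) without EPD 2, EPD 3, LPD 1 or LPD 2 (up to 0.0829). miR-423-5p (1.16, adjusted p = 0.0300) was lost without Control 1, any EPD library, LPD 1 or LPD 2 (up to 0.115) and miR-143-3p (0.93, adjusted p = 0.0415) without Control 1, Control 3, any EPD library, LPD 1 or LPD 2 (up to 0.133), and both on counts per molecule. With the replicate block miR-143-3p was lost as well (0.0619).

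edgeR called 108 miRNAs in LPD against EPD, 12 higher and 96 lower (132 at an unadjusted p under 0.05), of which 63 lower ones had no count in LPD. DESeq2 called 122 (31 higher, 91 lower) and limma-voom 98 (10 and 88). Fitting only the 2 groups gave 67 calls (11 higher, 56 lower), keeping only miRNAs with counts in all 9 libraries 35 (17 and 18), and counts per molecule 43 (9 and 34). In all, 154 miRNAs (52.4%) did not overlap, beside 10% by chance. Of the 63 absent from LPD, miR-324-5p had 221 ± 56.4 CPM in EPD and passed on counts per molecule (adjusted p = 0.0362), the only 1 of the 42 that could be tested there. As the molecules were estimated from the number of miRNAs without counts, this pass does not test its absence, which stays open. miR-664-2-5p had 95.7 ± 26.7 CPM in EPD, miR-324-3p 92.3 ± 17.3, miR-672-5p 80.8 ± 9.63, miR-134-5p 65.4 ± 32.4, miR-93-3p 62.5 ± 20.5, miR-99b-3p 52.1 ± 4.21 and miR-151-5p 50.3 ± 16.3. miR-802-5p, with 52.2 ± 19.7 CPM in EPD, lost its call without EPD 1, EPD 3, LPD 1 or LPD 2 (up to 0.0657). None of the 63 had a mean in EPD above the level of 3 molecules in LPD, so no fold is given. miR-503-3p fell from 53.3 ± 14.2 to 1.50 ± 2.60 CPM (adjusted p = 0.0163), lost without EPD 1 (0.0551) and on counts per molecule (0.404). Among miRNAs that had passed against Control, miR-223-3p had a log2 fold change of 0.34 (adjusted p = 0.547). miR-34a-5p fell from 623 ± 269 to 26.4 ± 45.7 CPM (-4.72, adjusted p = 0.0268), which was lost without EPD 2 (0.0797) or EPD 3 (0.0568). It stood at -4.10 without LPD 1, at -4.08 on counts per molecule and at -5.45 with the replicate block, and without LPD 3 no count of it was left in LPD. Its LPD value rested on about a single estimated molecule in LPD 3, so the size of this fall is not well determined either.

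Other miRNAs chosen in advance gave no call between the stages. In LPD against EPD miR-451-5p had a log2 fold change of -0.27 (adjusted p = 0.780; 0.95 without EPD 1, 0.02 with DESeq2 or its size factors, 0.03 over miRNAs with counts in all 9 libraries), miR-16-5p of 0.39 (0.531, without EPD 1 1.03), miR-23a-3p of 0.14 (0.745, without EPD 3 -0.01) and miR-122-5p of -0.01 (0.990). The last stood at 0.88 without EPD 3 and was positive in 8 other alternatives (0.02 to 0.33). miR-1-3p had 2.16 (adjusted p = 0.237; 3.999 without EPD 3, 0.26 without LPD 3) and miR-133a-3p 0.40 (adjusted p = 0.844; 1.74 without EPD 3, -1.51 without LPD 3, -0.38 with the replicate block, -0.03 without EPD 1, -0.02 without EPD 2). miR-7a-5p had -0.78 (adjusted p = 0.173), miR-155-5p 0.37 (0.531), miR-126a-3p 0.41 (0.382) and miR-150-5p -0.37 (0.388). miR-21-5p had 0.93 (adjusted p = 0.0977) and passed with DESeq2 size factors (0.0359), with DESeq2 (0.0151) and without LPD 1 (0.0465). miR-210-3p had -3.41 (adjusted p = 0.0718, -4.37 with the block) and passed without LPD 1 (0.00374), with DESeq2 (0.0251) and on counts per molecule (0.0229). miR-9a-5p had 0.998 (adjusted p = 0.664; 1.77 without EPD 1, -0.13 with the block) and was called lower without LPD 3 (adjusted p = 0.0366), which left no count of it in LPD.

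The let-7 list was also the only one to pass in LPD against EPD (higher, median log2 fold change 0.52, adjusted p = 0.0108, 3 of 9 called higher). The call was lost with an estimated correlation (adjusted p = 0.911), without LPD 1 (0.0553) or LPD 2 (0.0895), when only miRNAs with counts in all 9 libraries were kept (0.290) and on counts per molecule (0.0735). Epithelium had 10 of 18 members lower (adjusted p = 0.147; adjusted over the list alone, 11 lower and 1 higher) and passed without Control 1 (0.0399), without Control 2 (0.00881), when only miRNAs with counts in all 9 libraries were kept (0.0280) and on counts per molecule (0.0142). Called higher and lower were 1 and 5 erythrocyte members (adjusted p = 0.650), 2 and 2 platelet (0.177), 0 and 4 leukocyte (0.650), 0 and 2 liver (0.650), 0 and 1 muscle (0.575), 0 and 5 brain (0.650) and 0 and 5 Dlk1-Dio3 (0.650). They were 0 and 8 for Parkinson literature (0.837), 0 and 6 for inflammation (0.837), 0 and 3 for hypoxia with p53 (0.650), 1 and 7 for the miR-17 clusters (0.837), 0 and 1 for pancreas (0.837) and 3 and 3 for vessel wall (0.187). Over all tested miRNAs, 96 of 294 were called lower and 12 higher. All called Dlk1-Dio3 members and 4 of the called brain members had no count in any LPD library. Adjusted over the list alone, 7 erythrocyte, 6 Dlk1-Dio3, 10 Parkinson, 7 inflammation and 8 miR-17 members were lower, and no muscle member. fry called 7 lists.

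**Figure D5:**
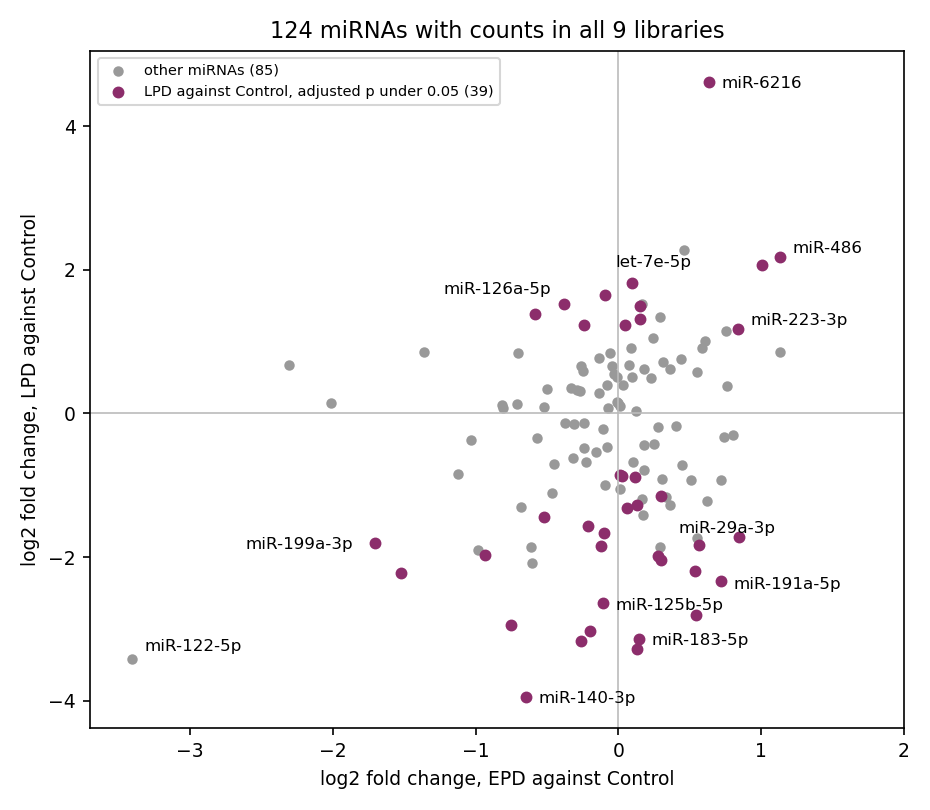
Each point is 1 of 124 miRNAs with counts in all 9 libraries, with the log2 fold change of EPD against Control on the horizontal axis and that of LPD against Control on the vertical axis. The 39 that passed in LPD against Control are purple and the other 85 grey.

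Taking the 3 groups together, 96 miRNAs differed (122 at an unadjusted p under 0.05). DESeq2 called 117 and limma-voom 90. Counts fell to 37 when only miRNAs with counts in all 9 libraries were kept, to 46 on counts per molecule and to 58 without LPD 2. Of the 96 miRNAs lower in LPD than in Control and the 96 lower than in EPD, 90 were the same, and of the 13 and 12 higher ones 10 were the same. Both comparisons use the same LPD libraries. For the shared change, EPD and LPD against Control, the log2 fold changes of 294 miRNAs correlated with r = 0.151, where unchanged groups simulated against the same controls gave 0.458 ± 0.067. It was 0.305 without Control 2, 0.253 without EPD 1, 0.251 without EPD 2, 0.262 without LPD 3, 0.0972 without Control 1, 0.226 over the miRNAs with counts in all 9 libraries and 0.244 on counts per molecule. Their covariance was 0.404, against 0.470 ± 0.101 in the simulations, and 0.215 against 0.187 ± 0.0499 over the 124 miRNAs with counts in all 9 libraries. For these 124, r in the fit of all miRNAs was 0.232, against 0.498 ± 0.0859. In the same direction changed 51.7% of the 294, against 66.0 ± 2.95%, and 50% of the 124, against 66.5 ± 4.16%. The covariance thus gave no sign of a common change beyond what shared controls give. For the 294 miRNAs, however, the correlation and the share in the same direction lay below all 100 simulations (lowest 0.313 and 59.5%). The simulations used 1 spread per miRNA for all 3 groups and may not match these data. A common change is therefore neither shown nor excluded. miR-199a-3p, at -1.71 in EPD and -1.80 in LPD, was lower than Control at both stages, but passed only in LPD.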

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

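The tests in this part on chance splits and on random loss of molecules were set before their results were seen, and all others, with the wider spread, the other scaling and the counts per molecule for random loss, were chosen after. The number of miRNAs that differed between the stages, 108, and the number of lists, 1, were put here because LPD and EPD were each compared with Control and gave different answers. There are 10 splits of 6 libraries into 3 and 3, the real one included. For EPD against Control all 10 gave a count of miRNAs as large as the real one (real 0, highest other 0). With a real count of 0 that outcome was fixed in advance. Only the real split reached its own count for LPD against Control (real 109, highest other 0) and for LPD against EPD (real 108, highest other 1). For the lists, a count as large as the real one came in 4 splits (real 6, highest other 7), 6 splits (real 1, highest other 5) and 6 splits (real 1, highest other 4). These numbers again include the real split. With 10 splits there are too few for a share under 0.05. For the 3 groups together 4 of 100 splits, the real one included, were as large as the real 96, with 102 as the highest other. The 5 splits that kept the LPD libraries together gave 93 to 102, and the 95 others at most 1.

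Many miRNAs had no count in LPD, such as miR-802-5p, miR-127-3p and miR-324-5p. Thinning the Control and EPD libraries to the LPD totals left at least 313 miRNAs detected, against at most 197 in LPD, so fewer reads alone did not give this. At 10 counts thinned libraries kept as few as 173 at the total of LPD 2 and 151 at that of LPD 3, against 144 and 158. A single molecule stood for an estimated 12.3 to 49.1 counts in LPD. The comparison at 10 counts therefore does not show how much of that drop went with the totals. The LPD libraries had at most 19.8% of their detected miRNAs at 1 to 9 counts, against at least 41.6% in the thinned ones, which is consistent with few molecules each read many times. The sources hold 0 measures of input RNA, so whether late rotenone lowered serum miRNA or less serum RNA was captured stays open.

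miR-122-5p took 44.3% of Control 2. The other liver miRNAs were higher there by a median of 1.92 log2, and 9 of 11 lay above both other controls, which suggests liver RNA in that sample. That argues against over-amplification of a single sequence. Whether liver injury, handling or another cause lay behind it stays open.

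miR-125b-5p, miR-140-3p and miR-191a-5p were among the miRNAs with counts in all 9 libraries that were lower in LPD. Of 124 miRNAs with such counts 28 had the 3 LPD libraries lowest of 9 and 12 had them highest, against 1.48 each by chance with equal spread and up to 15.5 (SD 3.68) if the LPD spread was far wider. With DESeq2 size factors 24 were lowest and 19 highest. On counts per molecule 23 of the 27 called lower miRNAs stayed past the threshold, with a median SE of 0.51 against 0.48 before. Most of these differences were thus larger than the counting error of the estimated molecules. Their median log2 fold change, -2.02 against -1.97 before, could hardly move, as each library was divided by 1 number. The 27 were picked from the same data, and the SD of 3.68 takes miRNAs as independent. Random loss of molecules as the whole cause is therefore not excluded. Amplification that depends on sequence, or another difference between library batches, could have given the same, as 0 Control or EPD libraries lie in the LPD range of counts per molecule, and that stays open.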

How the results depend on the processing

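The alternatives were fixed before the data were examined, except the filter on counts in all 9 libraries, counts per molecule and, for single miRNAs, library totals, which were chosen after seeing the data. The series matrix (0 differing values), limma on normalized values (the files hold counts) and a fit of only 2 groups for the 3-group test were not run. Totals and detection fell in every LPD library, so low miRNAs in LPD lie under the floor and depth limits what can be called there. When 1 library is left out, a group of 2 remains and the fit pools its spread with the others. The cause of the moves below was not tested.

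Calls of miRNAs in EPD against Control were 1 with DESeq2 and 1 over miRNAs with counts in all 9 libraries, and 0 to 1 when leaving out each library. In LPD against Control they were 38 over counts in all 9, 35 per molecule, 52 with only 2 groups, and 93 to 140 leaving out a library. In LPD against EPD they were 35, 43, 67 and 90 to 134. Over the 3 groups they were 37 and 46, and 58 (without LPD 2) to 116 leaving out a library.

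Lists called in EPD against Control were 0 with an estimated correlation, 0 with fry, 1 over counts in all 9, 2 without Control 2, 1 without EPD 1, and 1 to 7 leaving out a library. In LPD against Control they were 0, 11 and 0, with 4 without Control 2, 2 without LPD 1, and 1 to 4. In LPD against EPD they were 0 and 7, with 2 without Control 1 or Control 2, 0 without LPD 1 or LPD 2, and 0 to 2.

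The correlation for the shared change, EPD and LPD against Control, was 0.226 over counts in all 9 and 0.244 per molecule, and 0.0972 to 0.305 leaving out a library (Control 2 0.305, EPD 1 0.253, EPD 2 0.251, LPD 3 0.262). miR-9a-5p turned without LPD 3, to -7.97 against Control (range -7.97 to 0.95) and -7.39 against EPD (range -7.39 to 1.77). LPD 3 was the only LPD library with counts of it. These fits had no count of it in LPD, so -7.97 and -7.39 are not measured folds. With the replicate block miR-9a-5p also turned, to -0.69 against Control and -0.13 against EPD.

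With the replicate block the calls were 0, 101, 101 and 79, and the lists 5, 1 and 1. Libraries with the same number correlated in their deviations by -0.0959 to 0.0826, and 0 of 9 pairs passed 0.1.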

Other observations

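The tests on neighbouring genes in this part were chosen after the results were seen. In EPD miRNAs of the Dlk1-Dio3 cluster, such as miR-127-3p with 50.6, 33.9 and 59.6 CPM against 208, 38.3 and 124 in Control, and miR-382-5p with 86.8, 50.8 and 146 CPM against 305, 74.1 and 156, had lower values without passing. In both, Control 2 lay within the range of the EPD libraries.

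Hypothesis: miRNAs of 1 genomic cluster move together in EPD. Over 26 clusters of neighbouring miRNA genes the smallest adjusted p with an estimated correlation was 0.406, so none passed, which at 3 libraries per group leaves it open. With the preset correlation the cluster of miR-351, miR-322, miR-503, miR-542 and miR-450a was lower (8 of 8 members, median log2 fold change -1.67, adjusted p = 8.82e-04), and so was the cluster of miR-199a and miR-214 (adjusted p = 0.00236). fry called the cluster of miR-195 and miR-497 (3 of 3 members lower, adjusted p = 0.0119). Whether any of these moves in EPD could be tested with more animals per group.

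Hypothesis: miR-125b-5p, miR-140-3p and miR-191a-5p fall in serum during late rotenone exposure. Their log2 fold changes of -2.64, -3.95 and -2.33 in LPD against Control stayed past the threshold on counts per molecule, but no sample label gives input RNA (0 measures). Quantitative PCR with an added reference RNA in equal serum volumes would test it.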
